A study of Mus musculus with 16 samples.

How the data were processed

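The data were peak lists from chromatin immunoprecipitation followed by sequencing (ChIP-seq) in MC3T3-E1, a mouse pre-osteoblast cell line that can be driven to lay down mineralised matrix. Of the 16 samples, 14 had a peak list, 1 for each of 7 antibodies in each of 2 states of the cells. The antibodies were against RUNX2, the runt-domain transcription factor needed for bone formation, C/EBPβ, a basic leucine zipper factor, and the histone modifications H4K5Ac, H3K9Ac, H3K4me1, H3K4me3 and H3K36me3. The other 2 samples were input DNA, whose peak lists or reads were not analysed here. Per the labels' protocols, the undifferentiated cells were compared with cells kept for 15 days in 10 mM glycerol-2-phosphate and 50 µg/mL ascorbic acid, at passages 5 to 12, and the mineralised matrix of the differentiated cultures was removed before chromatin was prepared. All peak lists came from cells given ethanol vehicle for 3 h per the labels. The differentiated input was labelled as treated with 100 nM 1,25-dihydroxyvitamin D3, and it entered no comparison. The cell line and treatment label of the differentiated H3K36me3 sample was garbled, and its state was taken from its title. The protocol names H3K5Ac where the antibody label reads H4K5Ac, and the name of the antibody label was used.

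Reads were aligned with Bowtie to mm9 and peaks were called with HOMER, per the submitters' processing notes, and the versions and thresholds are not given in the sources used here. Per the labels, each list holds the merged peaks of biological replicates, and every peak name in the files records at least 2 merged peaks. The replicates cannot be seen separately, so each antibody and state is 1 list and no difference between states had a replicate check. The deposited score of each peak was the authors' own value. It was 0 for every RUNX2 and C/EBPβ peak and above 0 for the histone marks, and it was used only to rank peaks of a mark within its own list. All RUNX2 and C/EBPβ peaks had a fixed width of 201 bp in the deposited lists, and mark regions were of variable width with a minimum of 1001 bp. Read depth is unknown, because a peak list carries no read counts, and a difference in depth or in enrichment between the immunoprecipitations would change list lengths. Intervals given below are exact Clopper-Pearson 95% intervals for a share of peaks and Newcombe intervals for a difference of shares. They cover counting error only, and peaks and genes are not replicates.

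The mouse assembly NCBIM37, which is mm9, and the GENCODE vM1 annotation were used. No peak ended beyond its chromosome, no peaks of 1 list overlapped each other, and 1 undifferentiated RUNX2 peak with a start below 0 was clipped. The gene set held 22239 genes, made of 22238 protein-coding genes and Cebpd, which the annotation lists as a pseudogene and which was added by name, with 69848 transcription start sites (TSSs). Positions are 1-based. Peaks were shared when they overlapped by at least 1 bp. RUNX2 peaks of undifferentiated cells were called kept or lost by whether they overlapped a differentiated RUNX2 peak, and differentiated peaks without an undifferentiated partner were called gained. The background was the mean of 100 random placements of the second list on the same chromosomes outside assembly gaps of at least 1000 bp. Promoters were within 1 kb of a TSS. Each peak went to the gene with the nearest TSS within 100 kb. For a gene list, the share of members with a peak was placed among 10000 random lists of the same size, matched on deciles of the distance to the neighbouring TSSs and on H3K4me3 at the promoter, and that percentile describes these peak lists and is not a p-value. For H3K36me3 by class of RUNX2 change, 1000 lists matched in the same way were drawn. H3K36me3 of a gene was the percentage of the annotated gene body covered by H3K36me3 regions. Motifs were searched on both strands within 100 bp of the peak centre and in windows of the same size 1 kb to each side.

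The sample groups, the measures, 16 gene lists and 28 named genes were fixed before the data were examined. The named genes were the 28, plus the 10 genes with most undifferentiated RUNX2 peaks, the 10 with most lost and the 10 with most gained peaks, with ties broken by name because all scores were 0. For the same reason the rule for naming single top-scoring peaks gave no ranking and was not used. The values of 1 of the 28 genes are not reported here, though the totals include it. Other list members were named in list order, and members named for their H3K36me3 or for a gained peak were chosen after their values were seen. The settings varied by plan covered the overlap that counts as shared, mark regions, score ranking, merging of nearby peaks, chromosomes, promoter width, motif window and the assignment of peaks to genes. Random thinning of the longer list and other assignments of peaks to the 28 genes were added later. Overlap, motif, nearest-TSS and gene-list steps were tested on simulated data. A planted overlap of 40% between RUNX2 lists came back as 40.03% of 12661 peaks, and random gene lists drawn from 22239 genes had a mean percentile of 51.11. Of 4000 windows, 42.75% held a motif after planting, and 100% of the planted windows were found. The same search had found a motif in 18.77% of the windows before planting, and these are part of the 42.75%. Randomly placed RUNX2 peaks overlapped H4K5Ac at 105.8% of the mean of the placements, over 12661 peaks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9 were used.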

Results

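Binding of RUNX2, the master transcription factor of the osteoblast, was mapped in MC3T3-E1 mouse pre-osteoblasts before and after 15 days of osteogenic differentiation, together with C/EBPβ and 5 histone modifications. H4K5Ac and H3K9Ac are acetylations of active regulatory regions, H3K4me1 marks enhancers and promoter flanks, H3K4me3 marks active promoters, and H3K36me3 covers the bodies of transcribed genes. There was 1 merged peak list for each of the 7 antibodies in each of the 2 states, 14 lists in all. No comparison between states therefore had replicates, no p-value was computed, and the read depth behind each list is unknown. Shares are given with exact 95% intervals that cover counting error only.

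The first question, posed by the title of the series, was how the set of RUNX2 sites changed with differentiation. RUNX2 had 12674 peaks in undifferentiated cells and 6272 in differentiated cells, a ratio of 0.495. Around Spp1, which encodes the secreted matrix protein osteopontin, the number went from 7 to 4, around Alpl, the tissue-nonspecific alkaline phosphatase of mineralising cells, from 6 to 2, and around Smad7, an inhibitor of TGFβ signalling, from 5 to 0. C/EBPβ had 15622 and 10847 peaks, a ratio of 0.694. The marks did not move together, with ratios of 0.804 for H4K5Ac, 1.58 for H3K9Ac, 1.06 for H3K4me1, 1.18 for H3K4me3 and 0.972 for H3K36me3. H4K5Ac covered 339.8 Mb before and 264.7 Mb after differentiation, and H3K9Ac 52.6 Mb and 86.5 Mb. H3K4me3 had more but narrower regions, with 26.4 Mb covered in undifferentiated and 21.8 Mb in differentiated cells. H3K4me1 covered 341.7 Mb and 343.8 Mb, and H3K36me3 352.4 Mb and 350.2 Mb.

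Of the undifferentiated RUNX2 peaks, 4616 (36.4%, 95% interval 35.6 to 37.3) overlapped a differentiated RUNX2 peak and 8058 did not, against 0.111% at random positions. In the other direction 73.8% (72.7 to 74.9) of the differentiated peaks were already present in undifferentiated cells, and 1641 peaks (26.2%) were gained. With the longer undifferentiated list thinned at random to the length of the differentiated list this second share was 36.7%, a setting chosen after seeing the data. Thinning lowers a share of matches by construction, so the fall does not show what the share would be at equal depth. C/EBPβ kept 6732 of its undifferentiated peaks, or 43.1% (42.3 to 43.9), lost 8890 and gained 4109. RUNX2 minus C/EBPβ was -6.67 percentage points (-7.81 to -5.53) in the share kept, a share that the shorter differentiated list bounds, and in the other direction the order turned, with 62.1% of differentiated C/EBPβ peaks already present against 73.8% for RUNX2. The histone regions were kept at higher shares, 71.5% for H4K5Ac, 99.0% for H3K9Ac, 86.7% for H3K4me1, 95.8% for H3K4me3 and 86.4% for H3K36me3, and these wide regions also overlapped more at random, at 19.1%, 6.91%, 24.3%, 2.32% and 23.5%.

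**Figure D1:**
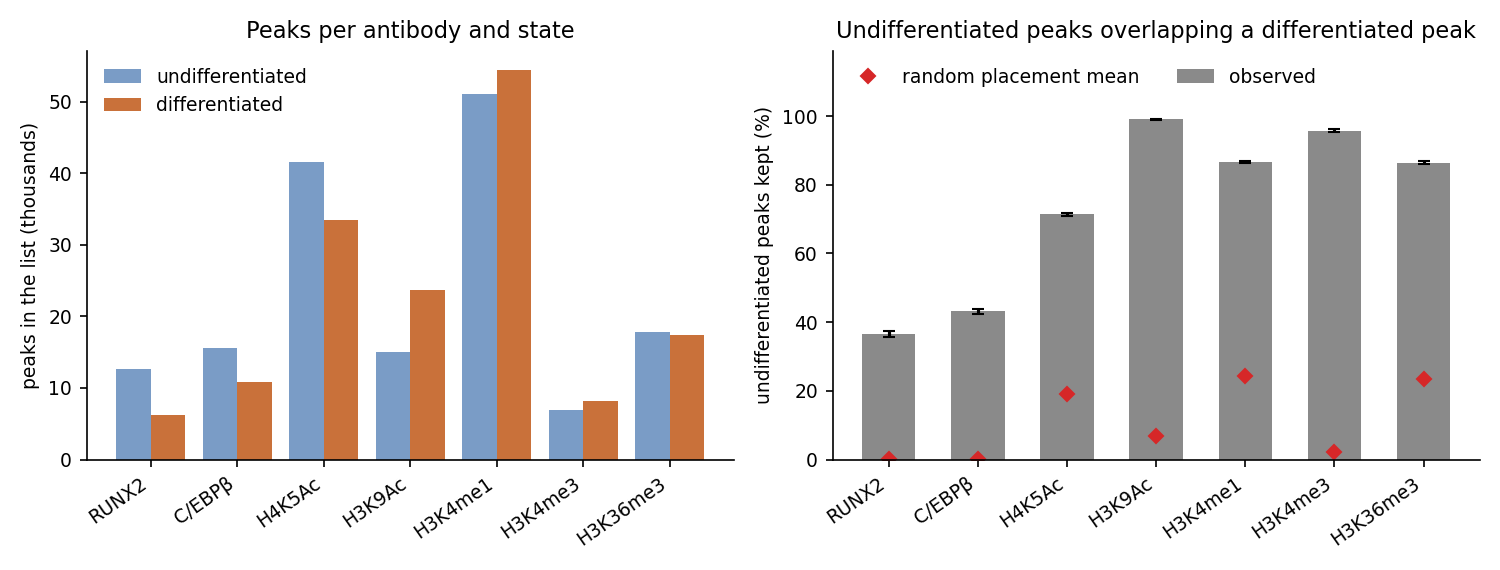
Number of peaks in the list of each antibody in undifferentiated and differentiated cells, and the percentage of undifferentiated peaks kept, with exact 95% intervals for counting error and the random placements beside them. RUNX2 had a ratio of list lengths of 0.495, which bounds its share kept, and kept 36.4%, and C/EBPβ had a ratio of 0.694 and kept 43.1%.

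The next question was which genes lay next to the changing RUNX2 sites. The 28 named genes were mostly of bone biology, and also held the housekeeping gene Gapdh and the cell cycle gene Ccnd1. Of the 28, 21 had at least 1 RUNX2 peak by nearest TSS in undifferentiated cells and 13 in differentiated cells. They had 89 peaks before and 36 after. There were fewer peaks at 20 of the genes, more at 0, and the same number at 1, which was Ibsp, encoding bone sialoprotein, with 1 peak in both states. Dlx5, Bglap, Bglap2, Enpp1, Bmp2, Sost and Gapdh had no RUNX2 peak by nearest TSS in either state. Bglap and Bglap2 also had no C/EBPβ peak and no region of any mark in either state. Whether reads could be placed at these 2 genes is unknown, so their lack of peaks does not show lack of binding. At the Runx2 gene itself (mm9, chromosome 17, 44632936 to 44951746), a peak at 44951445 to 44951645, 15 bp from a TSS, and an intronic peak at 44814741 to 44814941 were kept, and an intronic peak at 44843643 to 44843843 and a promoter peak at 44874157 to 44874357 were lost. Cebpb, the gene of C/EBPβ, went from 5 peaks to 1, and Cebpd, a related factor gene, from 4 to 2. Vdr, the vitamin D receptor gene, lost all 3 of its peaks, among them an intronic peak at 97717899 to 97718099 on chromosome 15. Twist1, a bHLH repressor of osteoblast maturation, went from 1 to 0.

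Among genes of the bone matrix, Col1a2, encoding a chain of type I collagen, had 12 RUNX2 peaks before and 7 after differentiation, and its promoter peak at 4455481 to 4455681 on chromosome 6 was kept. Col1a1, encoding the other type I collagen chain, had 7 and 6, with a gained peak at 94797599 to 94797799 on chromosome 11, 132 bp from the TSS, and a lost peak at 94800646 to 94800846. Spp1 kept its promoter peak at 104863915 to 104864115 on chromosome 5 and 3 upstream peaks at 104857836, 104855166 and 104837008, and lost peaks at 104862191, 104857422 and 104820065. Sparc, encoding osteonectin, went from 3 to 0, and Dmp1 and Phex, genes of phosphate handling and mineralisation, each from 1 to 0. The Dmp1 peak lay at the promoter, at 104630588 to 104630788. Mmp13, encoding collagenase 3, went from 1 to 0. Of the genes that act on osteoclasts, Tnfsf11, encoding RANKL, went from 5 to 1, keeping a distal peak at 78782943 to 78783143 on chromosome 14. Lost Tnfsf11 peaks at 78782715 to 78782915, 78783318 to 78783518 and 78784272 to 78784472 lay close beside this kept peak. Only the lost peak at 78730378 to 78730578 stood apart from it. Tnfrsf11b, encoding the RANKL decoy receptor osteoprotegerin, went from 2 to 0, losing a promoter peak at 54110175 to 54110375 on chromosome 15. Lrp5, a Wnt co-receptor, went from 4 to 2, and Ccnd1, encoding cyclin D1, from 5 to 4.

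The counts depended on how peaks were assigned to genes. Sp7, encoding osterix, a zinc finger factor downstream of RUNX2, had 4 peaks and 1 peak by nearest TSS and 6 and 4 within 20 kb of its TSS, but 3 and 4 over the gene body plus 10 kb, which turned its direction. Col1a1 had 3 peaks in both states within 20 kb and Ccnd1 had 2 in both. Vdr had 3 and 1 within 20 kb, and Twist1, Cebpb, Ibsp, Mmp13 and Tnfsf11 had none there, so that their peaks were distal. Sost, with none by nearest TSS, had 1 and 0 within 20 kb. Over the gene body plus 10 kb, 13 of the 28 genes had fewer RUNX2 peaks and 1 had more, and Runx2 itself had 8 and 3.

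**Figure D2:**
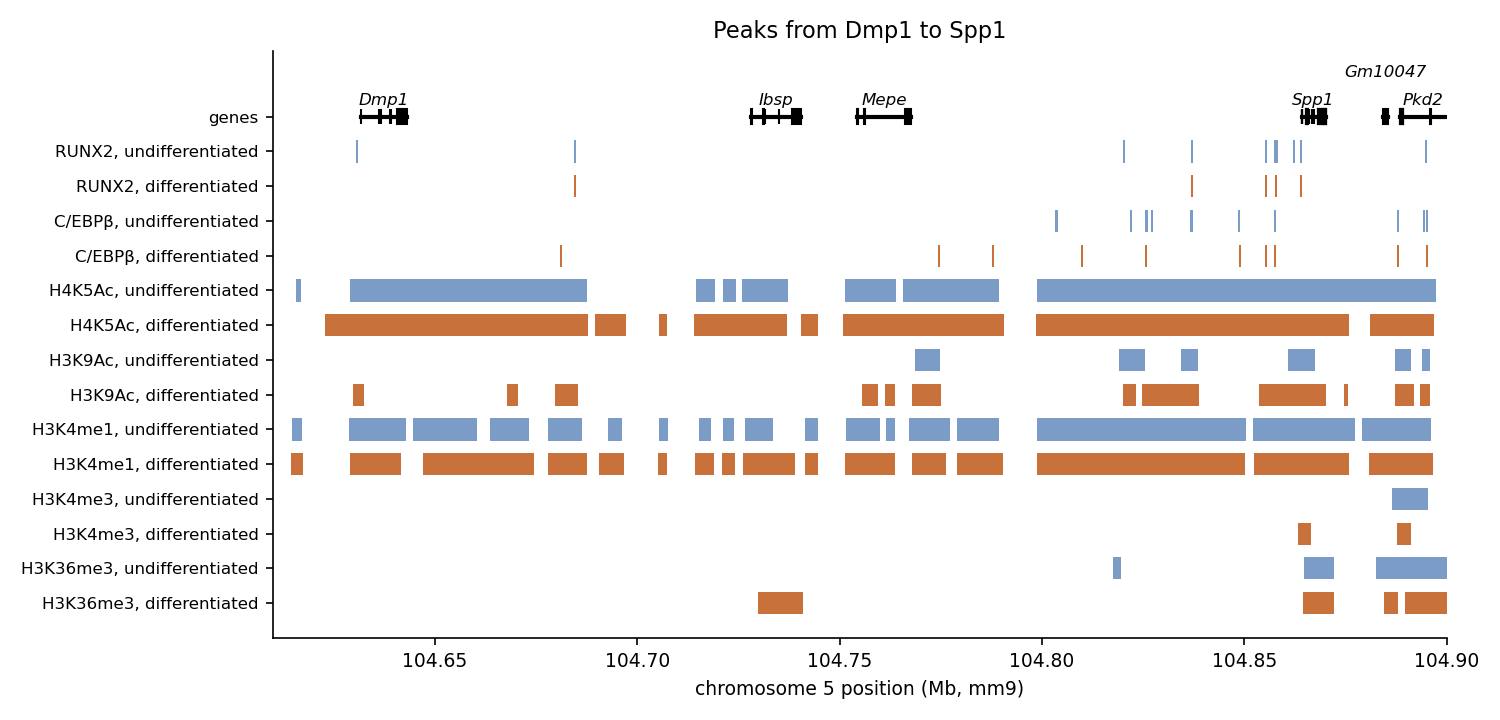
Map of chromosome 5 from 104610001 to 104900000 (mm9, in Mb on the horizontal axis) with Dmp1, Ibsp, Spp1 and the other genes of the window, the RUNX2 and C/EBPβ peaks of each state, drawn 500 bp wide, and the histone mark regions. The window held 10 RUNX2 peaks in undifferentiated and 5 in differentiated cells, and 13 and 10 C/EBPβ peaks.

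Across all 22239 genes, 6069 (27.3%) had a RUNX2 peak in undifferentiated cells and 3333 (15.0%) in differentiated cells, 2930 of them in both. Fewer RUNX2 peaks were assigned to 4403 genes after differentiation and more to 649. The genes with most undifferentiated RUNX2 peaks were Tns3, encoding a focal adhesion protein, with 17 before and 11 after, Bach2, encoding a transcriptional repressor, with 16 and 7, Mylk, encoding myosin light chain kinase, with 15 and 9, and Cald1, encoding caldesmon, and Ltbp1, encoding a protein that stores TGFβ in the matrix, each with 13 and 5. Adamtsl3 had 12 and 9, Col1a2 had 12 and 7, 4930558K02Rik had 12 and 5, and Bahcc1 and Gse1 each had 12 and 4. Losses of 9 peaks were seen at 4930558K02Rik, Bach2, Bahcc1, Cald1, Gse1 and Wwox, and losses of 8 at Ltbp1, Rara, the retinoic acid receptor alpha gene (11 and 3), Rgs3 (10 and 2) and Rnd3 (9 and 2). Tbc1d1, encoding a Rab GTPase-activating protein of glucose transport, gained 6 peaks and went from 5 to 10. Gadd45a, a stress response gene, Haao and Kcnma1, encoding a calcium-activated potassium channel, each went from 0 to 4. Prkce went from 2 to 5, Hhat from 9 to 11 and Tgfbr3, a TGFβ co-receptor gene, from 5 to 7, while Col4a2, with 8 in both states, Nrp2, with 7 in both, and Adamtsl3 exchanged 4 gained peaks for as many or more lost.

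Gene lists fixed beforehand placed these genes in groups. Of 24 osteoblast matrix and mineralisation genes, 19 had a RUNX2 peak in undifferentiated cells (79.2%, 57.9 to 92.9) and 13 in differentiated cells (54.2%, 32.8 to 74.5), both at the percentile 100 of matched random lists, whose means were 36.3% and 21.1%. Peaks were fewer at 16 members, more at 1 and equal at 3. Outside the 28 genes, Ank, a pyrophosphate transporter gene, had 3 and 2 peaks, Phospho1, a phosphatase gene of matrix vesicles, 1 in both states, and Omd and Ogn, encoding small leucine-rich proteoglycans, each 1 and 0. Of 24 osteoblast transcription factors, 18 had a peak before (percentile 99.9) and 11 after (percentile 97.2), with fewer peaks at 17 members, among them the homeobox genes Dlx3 (4 and 0) and Dlx6 (5 and 3), and more at 0. With distal peaks left out this group stood apart neither in undifferentiated cells, since within 20 kb 50% of its members had a peak in undifferentiated cells and over the gene body plus 10 kb 45.8%, at percentiles of 78.2 and 47.9, nor in differentiated cells, at percentiles of 89.0 and 76.5. Of 28 Wnt, BMP and TGFβ signalling genes, 20 had a peak before and 14 after (percentiles 99.6 and 98.5). Peaks were fewer at 14 of these genes, more at 1 and equal at 6. Examples were Lrp6 (2 and 1), Axin2 (3 and 1), Ctnnb1 (1 and 1) and Lef1 (2 and 1). Within 20 kb 12 of the 28 genes had an undifferentiated peak (percentile 61.3), and over the gene body plus 10 kb 13 (percentile 53.8). The differentiated percentiles were 81.0 and 84.4, while the osteoblast matrix list stayed at percentiles of 99.98 and 100 in undifferentiated and 99.89 and 99.11 in differentiated cells.

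Osteoclast coupling genes had peaks at 9 and 6 of 11 (percentiles 99.8 and 98.6), including Csf1, the macrophage colony-stimulating factor gene, with 9 and 6 peaks. In differentiated cells 4 of the 11 had a peak within 20 kb and also over the gene body plus 10 kb (percentiles 93.9 and 88.6). Matrix remodelling genes had peaks at 11 and 5 of 14 (percentiles 100 and 94.5; within 20 kb 8 and 5, percentiles 90.5 and 91.8), with Mmp9 at 1 and 0 and Mmp2, 1 of the 3 members with more, at 1 and 2. RUNX family and co-regulator genes had them at 8 and 7 of 10 (percentiles 93.4 and 98.3), with Runx1 at 8 and 6 and Runx3 at 7 and 5. Vitamin D pathway genes had peaks at 4 and 2 of 10 (percentiles 75.5 and 55.5), with Rxra at 10 and 6 peaks. This list depended on the assignment, with 7 and 6 of 10 within 20 kb (percentiles 97.52 and 99.66) and 5 and 4 over the gene body plus 10 kb. Cell cycle genes had them at 11 and 4 of 22 (percentiles 76.2 and 38.2), with Cdk1 at 2 and 1 and Mcm2, a replication licensing gene, at 1 and 0. Osteocyte genes had peaks at 4 and 0 of 8, and the count of 0 allows a share of up to 36.9%. Marker lists of other cell types had peaks at 3 and 3 of 12 adipocyte, 6 and 5 of 12 chondrocyte, 2 and 0 of 12 muscle, 4 and 3 of 12 haematopoietic, 3 and 2 of 9 endothelial and 2 and 0 of 12 neural genes, and housekeeping genes at 5 and 4 of 10. In differentiated cells the adipocyte list lay at percentile 96.9 and the haematopoietic list at 96.7 (99.2 within 20 kb), close to the 97.2 of the osteoblast transcription factors, while the adipocyte list was at 81.1 within 20 kb. In the thinned undifferentiated lists the mean share was 60.3% (41.7 to 75 over draws) for the osteoblast matrix list, against 54.2% in the full differentiated list, and 62.4% (45.8 to 75) against 45.8% for the transcription factor list. Matrix remodelling genes had 49% (21.4 to 78.6) against 35.7%, down from 78.6% in the full undifferentiated list, and osteocyte genes 25.9% (0 to 50) against 0. At equal length the differentiated share was above the mean of the draws, but within their range, for the chondrocyte (27.8% and 41.7%), adipocyte (16.7% and 25%), haematopoietic (16.1% and 25%), RUNX family (66.5% and 70%), housekeeping (37.8% and 40%) and endothelial (19.6% and 22.2%) lists, and this thinning was chosen after seeing the data.

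**Figure D3:**
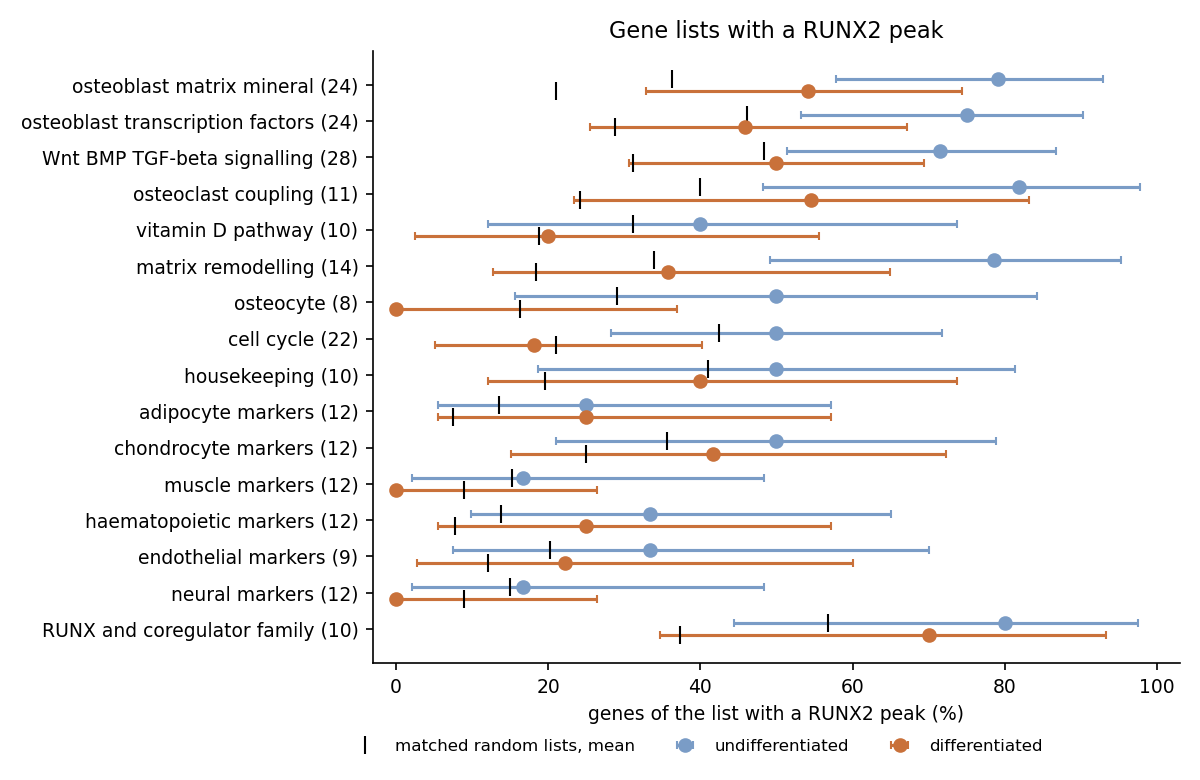
Percentage of the members of each gene list with at least 1 RUNX2 peak by nearest TSS, in undifferentiated and differentiated cells, with exact 95% intervals and the mean of matched random lists. The osteoblast matrix list went from 79.2% to 54.2%, with random means of 36.3% and 21.1%.

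The design also asked where the sites lie and in which chromatin. In undifferentiated cells 26.0% (25.2 to 26.7) of RUNX2 peaks lay at promoters, 31.9% in introns and 40.7% between genes, and in differentiated cells 18.5% (17.6 to 19.5), 35.1% and 44.6%, against 3.26% of random positions at promoters. Lost peaks were at promoters in 29.3% of cases, kept peaks in 20.2% and gained peaks in 13.8%. Lost promoter peaks included those of Dmp1, Tnfrsf11b and the pair at Smad7, at 75526279 to 75526479 and 75535254 to 75535454 on chromosome 18. C/EBPβ peaks lay at promoters in 14.7% and 12.7% of cases. With promoters taken as 5 kb around a TSS the differentiated RUNX2 share was 29.0% and the C/EBPβ shares were 26.2% and 24.5%.

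RUNX2 peaks lay in acetylated and H3K4me1 chromatin in both states. In undifferentiated cells 97.1% overlapped H4K5Ac, 96.6% H3K4me1, 55.0% H3K9Ac, 24.4% H3K4me3 and 24% H3K36me3, which was 6.91, 6.90, 22.6, 19.1 and 1.71 times the random placements. In differentiated cells the shares were 94.8%, 98.4%, 74.95%, 16.7% and 24.6%. The RUNX2 sites that were lost stayed in acetylated chromatin, for 7414 of the 7787 lost sites inside H4K5Ac before differentiation (95.2%, 94.7 to 95.7) were inside it afterwards. Of lost sites outside H3K9Ac before, 43.0% (41.4 to 44.6) lay inside it afterwards, as did 62.5% of kept and 35.99% of gained sites. Lost and kept sites had H3K9Ac at 54.7% and 55.4% before differentiation, a difference of -0.759 points (-2.56 to 1.04) that counting error covers, and at 73.6% and 83.0% afterwards, a difference of -9.43 points (-10.9 to -7.96). Gained sites already lay in H4K5Ac in 86.7% and in H3K4me1 in 89.3% of cases before differentiation. At Alpl all 4 lost RUNX2 sites, from 137297503 to 137348963 on chromosome 4, remained inside H4K5Ac and H3K4me1. H3K4me3 overlapped 26.9% of lost, 20.1% of kept and 11.5% of gained sites before differentiation, with 6.80 points (5.28 to 8.29) between lost and kept.

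**Figure D4:**
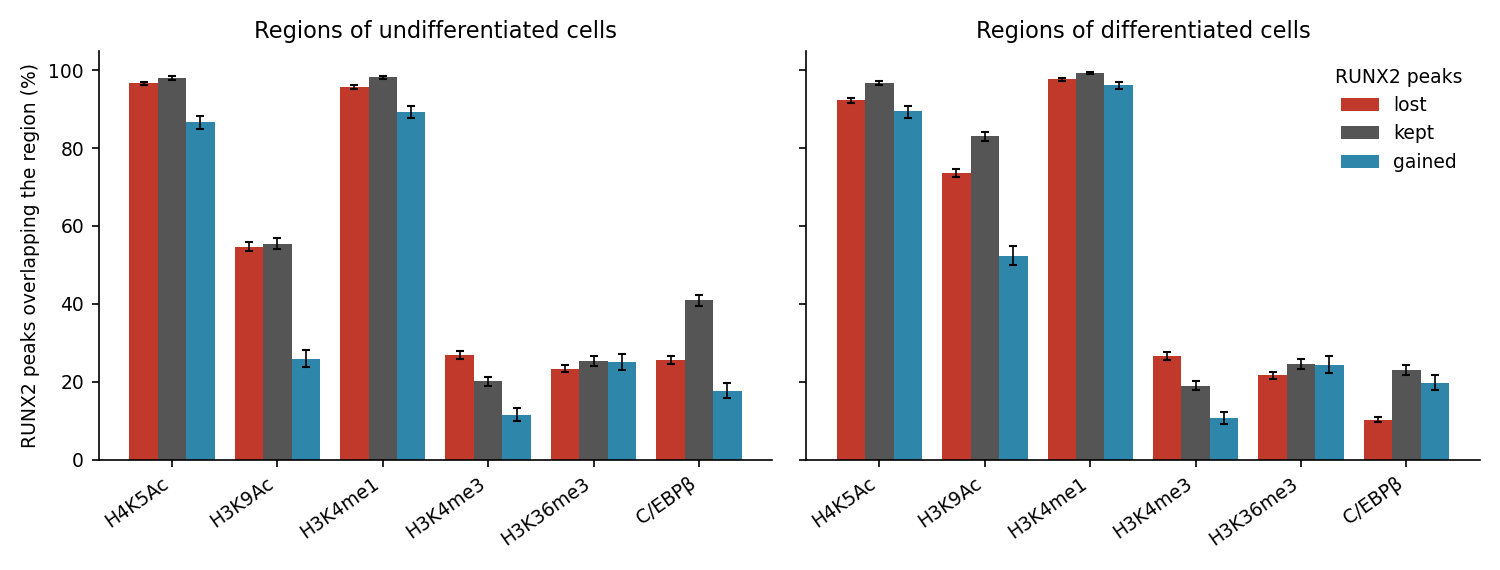
Percentage of lost, kept and gained RUNX2 peaks that overlap each histone mark or C/EBPβ in undifferentiated and in differentiated cells, with exact 95% intervals for counting error. H4K5Ac covered 96.6% of the lost peaks before and 92.3% after differentiation, and C/EBPβ 25.5% and 10.3%.

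C/EBPβ was mapped in the same cells to ask how often it shares sites with RUNX2. It overlapped 3944 RUNX2 peaks (31.1%, 30.3 to 31.9) in undifferentiated cells and 1390 (22.2%, 21.1 to 23.2) in differentiated cells, which was 116.4 and 121.1 times the random placements and 22.4 and 20.9 times placements inside H3K4me1 or H4K5Ac regions. In a comparison chosen after seeing the data, RUNX2 peaks with C/EBPβ were kept in 47.9% of cases (46.3 to 49.5) and those without it in 31.2% (30.3 to 32.2), a difference of 16.7 points (14.8 to 18.5). C/EBPβ peaks with RUNX2 were kept in 39.8% (38.3 to 41.4) and those without in 44.2% (43.3 to 45.1), a difference of -4.38 points (-6.14 to -2.60). Both factors were kept at 842 of the 3944 shared RUNX2 sites. Among the 28 genes C/EBPβ peaks went from 80 to 55, with fewer at 15 genes, more at 4 and equal counts at 9. Spp1 had 8 and 5, Col1a2 15 and 11, Cebpb 6 and 4, Runx2 5 in both, while Col1a1 had 4 and 5, Phex 2 and 4, Mmp13 2 and 3 and Ibsp 0 and 1. These 4 last genes had no gained RUNX2 peak except Col1a1. The shared fraction depended on the overlap rule. With the longer C/EBPβ list thinned to the length of the RUNX2 list it was 12.9% in differentiated cells. That setting was chosen after seeing the data, and thinning lowers a share of matches by construction.

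The sequence under the peaks was examined for the motifs of both factors. The RUNX core motif (TGYGGT) was found within 100 bp of 61.7% of undifferentiated and 71.1% of differentiated RUNX2 peaks, against 16.7% and 16.97% of side windows, ratios of 3.69 and 4.19. It was present at 56.1% of lost, 71.5% of kept and 66.4% of gained peaks, with a difference of -15.3 points (-17.02 to -13.63) between lost and kept. Away from promoters the shares were 64.3%, 74.5% and 69.5%, and the difference was -10.2 points (-12.0 to -8.27). At promoters they were 36.3%, 59.6% and 46.7%. The CEBP motif was found at 51.4% and 56.1% of C/EBPβ peaks before and after differentiation, and at 47.7% of lost, 56.1% of kept and 55.1% of gained C/EBPβ peaks. RUNX2 peaks with C/EBPβ had the CEBP motif in 26.1% of cases and those without in 10.2%, a difference of 15.9 points (14.4 to 17.4), while the RUNX motif was at 62.0% and 61.6%, a difference of 0.437 points (-1.40 to 2.26). C/EBPβ peaks with RUNX2 had the RUNX motif in 52.2% and the CEBP motif in 35.4% of cases, against 21.0% and 56.8% of those without. Other motifs at undifferentiated RUNX2 peaks were TEAD at 22.3% (side windows 10.8%), SP at 17.7% (4.83%) and AP-1 at 9.71% (3.51%). The bases G and C made up 51.55% of the sequence at these peaks and 45.73% in side windows. No motif share was corrected for this, which bears most on motifs made of G and C such as SP (GGGCGG). The ratio of RUNX motif to side windows was 1.98 and 2.15 with windows of 250 bp either side, and the CEBP ratio was 1.74 and 1.83, against 3.14 and 3.39 within 100 bp. Within 50 bp the RUNX ratios were 5.11 and 6.58 and the CEBP ratios 5.32 and 5.94.

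**Figure D5:**
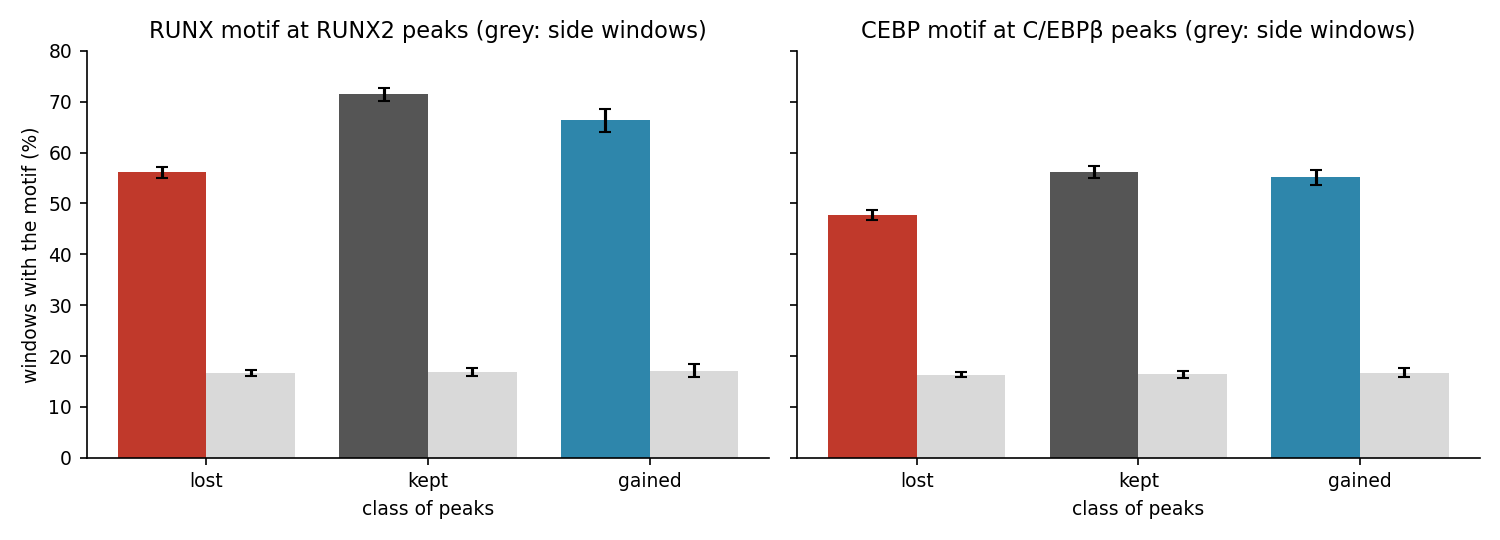
Percentage of lost, kept and gained RUNX2 peaks with a RUNX motif, and of C/EBPβ peaks with a CEBP motif, within 100 bp of the centre. Exact 95% intervals are drawn, and windows 1 kb to each side stand beside them. Lost RUNX2 peaks carried the RUNX motif in 56.1% and kept peaks in 71.5% of cases.

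The title of the series also relates the sites to gene expression, for which the peak lists hold H3K36me3 over gene bodies as a chromatin measure and no RNA values. Of the 28 genes, Ibsp went from 0 to 86.5% of its body covered and Mmp13 from 0 to 90.3%, Runx2 from 78.8% to 91.7%, Sp7 from 93.8% to 99.8% and Spp1 from 90.4% to 96.1%, although 4 of these 5 genes had fewer RUNX2 peaks and Ibsp an equal number by nearest TSS. Vdr went from 93.3% to 62.0%, Cebpb from 42.2% to 6.98% and Cebpd from 49.8% to 0. Col1a1 and Gapdh were at 100% in both states, and Alpl, Dmp1, Phex and Tnfsf11 at 0 in both. In the osteoblast matrix list 2 of 24 genes, Ibsp and Phospho1 (0 and 61.1%), had at least 20 points more and 1, Omd (79.6% and 37.4%), had at least 20 points less. In the osteoblast transcription factor list 2, Dlx3 (0 and 26.0%) and Zfp521 (74.5% and 98.2%), had more, and 4, Vdr, Cebpb, Cebpd and Junb (61.5% and 0), had less. In the cell cycle list Ccnb1, the cyclin B1 gene, went from 94.1% to 0 and Cdkn1a, encoding the inhibitor p21, from 96.2% to 71.5%, and no member gained 20 points. The Wnt, BMP and TGFβ list had 2 such gains, Lef1 (2.99% and 28.9%) and Tcf7 (34.2% and 81.6%), both encoding Wnt effector proteins, and 3 such losses, Bmp4 (100% and 49.1%) and the BMP target genes Id1 (70.6% and 0) and Id2 (55.5% and 0). Adipocyte, muscle and neural lists had a mean of 0 in both states.

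Promoter H3K4me3 was found at 7767 genes before and 8907 after differentiation, with 325 genes marked before only and 1465 after only. In the osteoblast matrix list it went from 10 to 14 genes, new at Spp1, Phospho1, Lum and Bgn, and in the transcription factor list from 17 to 15, with Sp7, Twist2 and Fosl1 no longer marked and Msx1 newly marked. In a comparison chosen after seeing the data, short genes lost H3K36me3 more often than long genes, since 10.4% (8.80 to 12.1) of genes under 5 kb with at least 20% of their body covered lost 20 points or more, against 4.02% (3.62 to 4.45) of longer genes, and Cebpb, Cebpd, Junb, Id1 and Id2 are under 5 kb.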

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

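Of 256 recomputed values, 182 counted as the same and 74 as moved. Same meant inside the 95% interval of the value as reported, or for counts within 1.5 times it. Ratios of covered length had no interval and counted as the same only if equal after rounding. Only ratios of list lengths, covered lengths and motif shares could reverse, by crossing 1, and 0 did. Counts at single genes were not among the 256 values, and of these counts that of Sp7 turned from fewer to more RUNX2 peaks over the gene body plus 10 kb. Random thinning, the restriction of overlaps to chromosomes 1 to 19 and X, and other assignments for the 28 genes were chosen after seeing the data. The planned ranking by score (or by length) was not run for RUNX2 and C/EBPβ, whether for overlaps, mark shares or gene lists, because all their scores were 0 and all their widths equal. None of the 17 values restricted to chromosomes 1 to 19 and X moved. The cause of each shift was not tested unless the alternative itself fixes it. Depth is unknown and limits every list length.

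With 50% of the shorter peak covered, RUNX2 kept 33.9%, 68.6% of its differentiated peaks were already present, C/EBPβ kept 42.3%, and RUNX2 shared 22.7% and 17.6% of its peaks with C/EBPβ before and after differentiation. With peaks widened by 500 bp these were 40.5%, 76.7%, 46.3%, 41.6% and 28.5%. With the longer list thinned to the length of the shorter, which lowers a share of matches by construction, already present fell to 36.7% and sharing was 25.3% and 12.9%. Within 1 kb merged, the peak and covered ratios were 0.513 and 0.463 for RUNX2 and 0.718 and 0.658 for C/EBPβ. The marks kept 82.1% (H4K5Ac), 90.03% (H3K9Ac), 84.6% (H3K4me1), 90.3% (H3K4me3) and 87.7% (H3K36me3) at equal lengths by score, and 72.1%, 99.5%, 85.2%, 82.9% and 90.8% in the higher-scoring 50% of each list. Promoters of 5 kb held 36.3% and 29.0% of RUNX2 and 26.2% and 24.5% of C/EBPβ peaks.

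With mark regions widened by 500 bp, undifferentiated RUNX2 peaks lay in H3K4me1 in 97.53% and in H3K36me3 in 31.0% of cases, and differentiated peaks in H3K36me3 in 30.7%. H3K4me1 then covered 96.8% of lost and 98.8% of kept sites before and 98.1% of lost sites after differentiation. H3K36me3 covered 30.5%, 31.95% and 28.4% of lost, kept and gained sites before and 28.8%, 31.7% and 27.9% after, and C/EBPβ 33.7%, 47.6% and 22.6% before and 14.3%, 27.1% and 24.01% after. With the peak centre inside the region, H3K36me3 held 23.2% of undifferentiated RUNX2 peaks, and C/EBPβ 18.1%, 30.6% and 13.3% of lost, kept and gained sites before and 7.32%, 17.6% and 15.7% after. Motif ratios to side windows, before and after, were 1.98 and 2.15 (RUNX) and 1.74 and 1.83 (CEBP) within 250 bp, and 5.11, 6.58, 5.32 and 5.94 within 50 bp. Within 20 kb 50% of the osteoblast transcription factors had an undifferentiated RUNX2 peak, and over the gene body plus 10 kb 45.8%. No paired analysis was possible because the labels give no replicate numbers and each list already merges the replicates.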

Other observations

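In this part the comparison with H3K9Ac, the share of lost sites still in H4K5Ac and the comparison of the X chromosome were tests chosen after the results were seen, and the genes in the first paragraphs were chosen after their values were seen. Among genes of at least 5 kb, H3K36me3 newly covered Col15a1, encoding a basement membrane collagen (1.9% before and 99.2% after differentiation), Slc40a1, encoding the iron exporter ferroportin (0 and 96.5%), Htra1, encoding a secreted serine protease (0 and 85.7%), and Col11a1, encoding a fibrillar collagen chain (0 and 63.3%). Pth1r, the parathyroid hormone receptor gene, went from 41.5% to 81.0%, and its RUNX2 peaks from 2 to 4. Runx3, a second runt-domain gene, went from 49.0% to 94.3% of its body with 7 and 5 RUNX2 peaks. Abca2, encoding a lipid transporter, went from 0 to 89.1%, and Plxnb1, encoding a semaphorin receptor, from 0 to 87.9%.

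Single genes with large losses of H3K36me3 were of several kinds. Ska1, a kinetochore gene, went from 93.5% to 0, Kifc1, a kinesin gene, from 92.6% to 0 with 2 and 0 RUNX2 peaks, Cenpm from 92.2% to 0, Cenph from 91.5% to 0 and Asf1b, a histone chaperone gene of S phase, from 85.7% to 0. Panx3, encoding a channel protein of osteoblasts and chondrocytes, went from 83.7% to 0 with 2 and 1 RUNX2 peaks, and Col2a1, the cartilage collagen gene, from 66.1% to 0 with 3 and 0. The cell cycle list as a whole did not move this way, with 2 of 22 members down by 20 points or more, a mean of 95.4% before and 89.8% after, and Top2a at 99.4% and 99.9%.

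RUNX2 lists were shorter after differentiation. Loss of the called H4K5Ac region was argued against for most lost sites. Of the lost sites in H4K5Ac, 95.2% (94.7 to 95.7) remained in it, against 98.2% (97.7 to 98.5) of kept sites. Lost sites thus left H4K5Ac more often than kept sites. Overlap with a called region cannot show the level of acetylation at a site, so a fall in that level stays open. A fall of weaker sites below the calling threshold of the RUNX2 immunoprecipitation had the lower motif share it needs, -15.3 points (-17.02 to -13.63) at lost against kept sites, and it may account for part of the loss, whether the cause was library depth, antibody yield or less RUNX2 on chromatin. A poorer yield of differentiated chromatin cannot be told apart from the state of the cells, because depth is unknown and the lists moved both ways, with H3K9Ac 1.58 times as long and H4K5Ac 0.804 times, and a biological decline of RUNX2 stays open as untested.

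RUNX2 and C/EBPβ peaks coincided. Regions that attract reads whatever the antibody were argued against for the RUNX2 peaks. Shared undifferentiated RUNX2 peaks had the RUNX motif 45.4 points (43.6 to 47.1) more often than side windows. Shared C/EBPβ peaks had the CEBP motif 19.6 points (17.95 to 21.33) more often than side windows. The RUNX motif cannot tell whether the C/EBPβ reads at shared sites were specific, so this explanation stays open for them. Open sites with AP-1 motifs had the excess they need, 2.51 points (1.37 to 3.69), but only 11.4% of shared and 8.93% of other RUNX2 peaks carried the motif, so they could cover a minority of the sites at most. Counted over undifferentiated C/EBPβ peaks there was no such excess, with 11.3% (10.3 to 12.3) of shared and 11.1% (10.5 to 11.7) of other peaks. In differentiated cells the shares were 11.65% of shared and 9.46% of other RUNX2 peaks, but 11.17% of shared and 12.85% of other C/EBPβ peaks. C/EBPβ peaks shared with RUNX2 carried their own motif 21.4 points less often than the others, a difference of -21.4 (-23.1 to -19.6).

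A hypothesis tested was that genes which gained and did not lose RUNX2 peaks, called gain-only, gained H3K36me3. The 495 such genes of at least 5 kb changed by a mean of 2.86 points, outside the central 95% of 1000 matched random lists (-0.706 to 0.970), with 33 genes up and 8 down by 20 points or more. The 3631 genes that lost and did not gain peaks changed by 0.172 points, with 97 up and 99 down. That lay inside the central 95% for that class, -0.0495 to 0.495. The 1043 that kept and did not lose peaks changed by 0.638, with 40 up and 22 down, inside -0.348 to 0.806. Genes of the gain-only and loss classes could also have kept peaks. A gene that kept and gained peaks without loss counts in both the gain-only and the kept class. The 10798 genes with no RUNX2 peak changed by -0.0935, below their own central 95% of 0.0386 to 0.246. Lying outside was thus not particular to gain-only genes, though these lay above and the genes without a peak below. Whether these deviations were independent of each other was not tested, so the second does not show that the first was unspecific. The gain-only relation may reflect the opening of a whole region as well as action of RUNX2, which was not tested, and the median change was 0 in both groups.

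H3K36me3 over genes of the X chromosome stood apart, since 60 of 252 X-linked genes of at least 5 kb with 20% or more of their body covered (23.8%, 18.7 to 29.6) lost 20 points or more, against 294 of 8622 on chromosomes 1 to 19 (3.41%, 3.04 to 3.82). H3K36me3 on X covered 9.45 Mb before and 7.21 Mb after differentiation, a ratio of 0.763, against 1.00 on chromosomes 1 to 19, and X-linked losses included Hdac6 (93.8% and 0) and Fancb (91.1% and 0). H3K4me3 regions on X numbered 122 before and 223 after, a ratio of 1.83 against 1.17 on chromosomes 1 to 19, H4K5Ac had 838 and 646, a ratio of 0.771 against 0.805, and C/EBPβ had 221 and 193, a ratio of 0.873 against 0.692. H3K9Ac (1.32 against 1.59), H3K4me1 (0.952 against 1.07) and RUNX2 (0.436 against 0.496, with 94 and 41 peaks on X) also had lower ratios there. Relative to chromosomes 1 to 19, the ratio on X was thus higher for H3K4me3 and C/EBPβ and lower for all other antibodies. No interval was computed for these ratios, and counting error may cover the smaller differences, such as those of RUNX2 and H4K5Ac. The number of X and Y copies in the cultures was not measured in these lists. The Y-linked Eif2s3y went from 97.8% to 0 in H3K36me3, while its promoter had H3K4me3 only after differentiation. Regions on Y numbered 7 before and 2 after for H3K36me3, 3 and 5 for H3K4me3, 5 in both for H4K5Ac, 5 and 4 for H3K9Ac and 1 and 0 for H3K4me1. RUNX2 had 13 peaks on the mitochondrial chromosome in undifferentiated cells and 0 in differentiated cells.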
